A study of Mus musculus with 22 samples.

How the data were processed

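Chromatin immunoprecipitation of H3K4me3 and H3K27me3 was done on purified neocortical cells of C57BL/6JOlaHsd mice with a kit for low cell numbers, and libraries were made with a MicroPlex kit, per the labels' protocols. Samples were grouped by the cell type and mark in their labels, which gave 10 groups of 2 samples and 2 Input samples. The submitters' processing notes name Bowtie 1.0.0, MACS2, bedtools and genome build mm9. The Input samples were not analysed here.

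The deposited values were 10 peak lists, 1 per cell type and mark. Per the peak names in the lists, each was called on combined samples, so replicates could not be compared, no test between cell types was possible and no replicate could be left out. Most names mention duplicate removal. The aRG-P H3K27me3 list came from a combined file whose name says that a set was excluded, and the N H3K27me3 list from reads extended by 200 bp, per the peak names, so these lists were made differently from the rest. Per the file headers, the lists hold peaks near transcripts, and the 2 apical radial glia H3K4me3 headers add a window of 2000 bp. Gaps in the peak numbers showed that 8.63 to 17.8% of H3K4me3 calls and 26.5 to 36.6% of H3K27me3 calls were not in the lists used here. Differences between lists can come from such steps. For H3K4me3, the authors' peak caller gave a fold enrichment (a ratio to background) and −log10 p and −log10 q values per peak. For H3K27me3, the deposited columns are called a score here, since their meaning could not be settled. Column 9 exceeded column 8 in every peak, and the 3 columns ranked the peaks almost alike (lowest Spearman correlation 0.997). Fold enrichment and scores were used to describe, rank or filter peaks within a list, and medians of fold enrichment given for several lists do not measure a change. The exception is a common lowest H3K27me3 score, which assumes scores comparable between lists. Read depth is unknown.

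Peaks were compared by overlap of at least 1 bp with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. A peak counted as lost or gained when no peak of the other list overlapped it. The share for a pair is the number of peaks of both lists that overlap a peak of the other list, over all peaks of both. Lost from progenitors means an aRG-N peak that overlapped peaks of NEC, aRG-P and bRG and none of N, and gained in N means an N peak overlapping none in any of the 4 progenitor lists. Shares have exact Clopper-Pearson 95% intervals. Random overlap came from 100 placements of 1 list on its own chromosomes with widths kept. Placements were not kept near transcripts, as the listed peaks are, so unrelated sites near transcripts could also exceed the random overlap. Regions across cell types were made by joining peaks that shared at least 1 bp.

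Named regions were the 3 lost and 3 gained per pair and mark with the highest fold enrichment (H3K4me3) or greatest length (H3K27me3) and no peak of that mark within 5000 bp in the other list. A named region is called present, marked, shared or found in a further list when any peak of that list overlapped it. Such a peak need not span the region. Single regions described beside them, such as the NEC H3K4me3 peak inside the chromosome 8 domain, were chosen after their values were seen. The comparisons, this rule and most of the other settings were fixed before the data were examined. The reference table held GRCm38.p6 genes, another build than mm9, so regions are given by position without gene names. States of gene promoters and gene lists, with their alternatives, were therefore not analysed here.

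Alternatives were a −log10 q of at least 5 for H3K4me3, peaks joined across gaps up to 3000 bp, an overlap of at least 50%, no peak within 5000 bp, and lists cut to the length of the shortest list of the mark. The cut kept the highest −log10 p for H3K4me3 and, in place of the planned −log10 p, the highest first score for H3K27me3. For a pair of cut lists, losses and gains differ only where a peak overlaps several peaks of the other list. The cut therefore cannot show a net loss or gain between them. The planned −log10 q of at least 3 for H3K27me3 removed no peak on any column. A common lowest H3K27me3 score of 15.8 and a restriction to autosomes were added after seeing the data.

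The overlap calls were tested on simulated lists made from the aRG-N lists, from which 200 peaks were removed and to which 200 were added. All 200 removed and all 200 added peaks were called for H3K4me3 (14801 peaks) and for H3K27me3 (6830 peaks), and no other peak was called. On chromosome 19 the calls for 499 H3K4me3 and 227 H3K27me3 peaks matched a direct comparison of all pairs.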

Results

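The series profiled 2 histone marks in purified cells of the developing mouse neocortex. H3K4me3, a mark of active and poised promoters, and H3K27me3, the mark laid down by Polycomb repressive complexes, were mapped by chromatin immunoprecipitation and sequencing. Neuroepithelial cells (NEC), the founder progenitors of the cortex, came from E9.5 embryos. The other 4 cell types came from E14.5 embryos, E standing for embryonic day. They were proliferative apical radial glia (aRG-P), neurogenic apical radial glia (aRG-N), basal radial glia (bRG) and neurons (N). Radial glia are the progenitors that descend from neuroepithelial cells, apical ones dividing at the ventricle and basal ones away from it. The 20 immunoprecipitated samples formed 10 groups of 2, and 2 further samples were Input DNA pooled from both ages. One peak list per cell type and mark was analysed, each called on combined samples, so no value below has a spread between replicates and no difference between cell types was tested. The read depth behind each list is unknown. Positions are given 1-based in mouse build mm9. Sites called strongest or longest in a comparison were ranked among peaks with no peak of that mark within 5000 bp in the other list.

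The H3K4me3 lists were of similar length in the 5 cell types, and the H3K27me3 lists were not. H3K4me3 peaks numbered 17867 in NEC, 15982 in aRG-P, 14801 in aRG-N, 15085 in bRG and 15759 in N. H3K27me3 peaks numbered 9460 in NEC, 5075 in aRG-P, 6830 in aRG-N, 3476 in bRG and 5734 in N. The H3K27me3 peaks covered 29.4 Mb in NEC, 26.0 Mb in aRG-N and 22.4 Mb in N, against 17.0 Mb in aRG-P and 12.6 Mb in bRG. H3K4me3 covered 20.3 Mb in NEC and between 11.8 Mb in aRG-P and 15.6 Mb in aRG-N among the E14.5 lists. The median fold enrichment of H3K4me3 peaks, a value the authors' peak caller gave, was 18.7 in NEC, 8.997 in aRG-P, 11.8 in aRG-N, 8.53 in bRG and 8.26 in N. A list made with a higher enrichment can hold weaker sites, so list lengths do not rank the cell types by the amount of a mark.

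**Figure D1:**
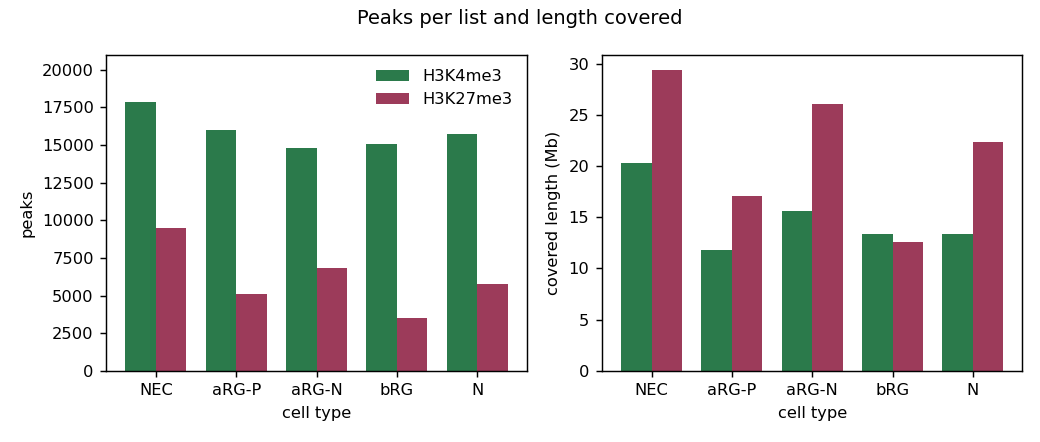
Number of peaks (left) and genome length covered in Mb (right) for each of the 5 cell types, with H3K4me3 in green and H3K27me3 in purple. The bars are single peak lists without replicates. H3K27me3 ranges from 3476 peaks in bRG to 9460 in NEC.

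In the lists as deposited, most H3K4me3 regions and a minority of H3K27me3 regions had a peak in all 5 cell types. When peaks of all cell types that touched were joined, 17229 H3K4me3 regions resulted, of which 11690 (67.9%) had a peak in all 5 lists. Of 13700 H3K27me3 regions, 2251 (16.4%) had a peak in all 5. On the autosomes alone that share was 22.4%. The short bRG list of 3476 peaks limits these H3K27me3 shares. Of its peaks, between 76.7% (in NEC) and 91.5% (in N) were found in each of the other lists. A share for all 5 lists at equal length was not computed. NEC alone accounted for 2722 H3K4me3 and 4872 H3K27me3 regions, and 3044 of the latter lay on chromosome X. H3K27me3 regions found in a single list also numbered 1578 in aRG-N, 942 in N, 650 in aRG-P and 111 in bRG.

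Pairs of E14.5 cell types shared between 91.5% (aRG-P and N) and 93.7% (aRG-N and bRG) of their H3K4me3 peaks. Pairs with NEC shared between 85.5% (with aRG-P) and 88.7% (with aRG-N). For H3K27me3 the E14.5 pairs shared between 58.1% (aRG-N and bRG) and 66.1% (aRG-P and bRG), and NEC shared between 40.3% (with bRG) and 49.8% (with aRG-N). The 95% exact binomial interval of the largest H3K27me3 value was 65.1 to 67.1%. Such intervals cover counting error only. Randomly placed peaks of the same widths met the other list in at most 3.02% of cases in any placement. These placements were not kept near transcripts, as the lists are, which lowers this value. In lists cut to equal length NEC shared 90.1 to 93.1% of H3K4me3 peaks with the E14.5 lists, which shared 91.3 to 93.4% with each other. For H3K27me3 these values were 62.0 to 66.7% and 73.2 to 79.2%. The lowest E14.5 pair was then aRG-P and bRG and the highest bRG and N, so the order of H3K27me3 pairs depended on list length.

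**Figure D2:**
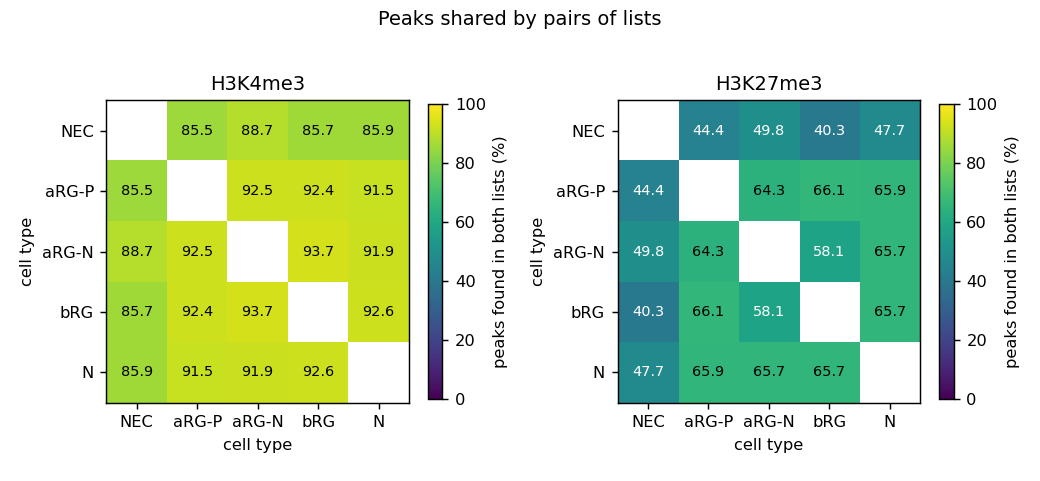
Percentage of the peaks of both lists of a pair that overlap a peak of the other list, for H3K4me3 (left) and H3K27me3 (right), with cell types on both axes. H3K4me3 pairs lie between 85.5% (NEC and aRG-P) and 93.7% (aRG-N and bRG), and H3K27me3 pairs lie between 40.3% (NEC and bRG) and 66.1% (aRG-P and bRG). Lists are as deposited, and the order of H3K27me3 pairs changed in lists of equal length.

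The step from NEC to aRG-P asked what changes between the early neuroepithelium and the later proliferative progenitor. At the 3 named NEC H3K4me3 sites with the highest fold enrichment the mark was absent in all 4 E14.5 lists, where H3K27me3 was present. At 2 of them H3K27me3 was absent in NEC. The NEC peak with the highest fold enrichment and no aRG-P peak nearby, on chromosome 4 from 133571168 to 133575153, had a fold enrichment of 51.7. The next, on chromosome 14 from 49281168 to 49287289, had 43.8. Both regions carried no H3K27me3 peak in NEC and carried one in aRG-P, aRG-N, bRG and N. Another region, on chromosome 17 from 86020069 to 86026069 with a fold enrichment of 43.3, had H3K27me3 in all 5 lists.

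The opposite exchange was seen on chromosome 8. An H3K27me3 domain of 80.9 kb, from 87257975 to 87338904, was present in NEC alone. Inside it, an H3K4me3 peak from 87293814 to 87296330 (fold enrichment 9.42) was present in aRG-P and overlapped in each of the other E14.5 lists, and was absent in NEC. NEC H3K4me3 within this domain was a single short peak from 87324323 to 87324505. Other H3K27me3 domains present in NEC and absent in aRG-P were 44.7 kb long on chromosome 18 (37884502 to 37929188) and 33.1 kb long on chromosome 1 (42739894 to 42772996). The first overlapped an H3K27me3 peak in aRG-N and N, the second in N. H3K27me3 domains absent in NEC and present in all 4 E14.5 lists measured 34.4 kb on chromosome 11 (35349539 to 35383981), 29.6 kb on chromosome 9 (69661653 to 69691207) and 23.4 kb on chromosome 3 (96125754 to 96149167). The last of these overlapped an H3K4me3 peak in NEC and none at E14.5.

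In total, 4498 NEC H3K4me3 peaks (25.2%, interval 24.5 to 25.8%) had no overlapping aRG-P peak, and 419 aRG-P peaks (2.62%) had none in NEC. The unshared NEC peaks were weak, with a median fold enrichment of 6.90 against 23.6 for shared ones. Of them, 1379 overlapped H3K27me3 in aRG-P, and 139 did so without H3K27me3 in NEC. For H3K27me3, 6307 NEC peaks were absent in aRG-P, 3386 of them on chromosome X, and 1769 aRG-P peaks were absent in NEC. In lists of equal length these H3K27me3 counts were 1361 and 1278, and the H3K4me3 counts were 2365 and 544. At equal length, losses and gains differ only where a peak overlaps several peaks of the other list. Neither pair of counts can therefore show whether losses outnumbered gains.

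**Figure D3:**
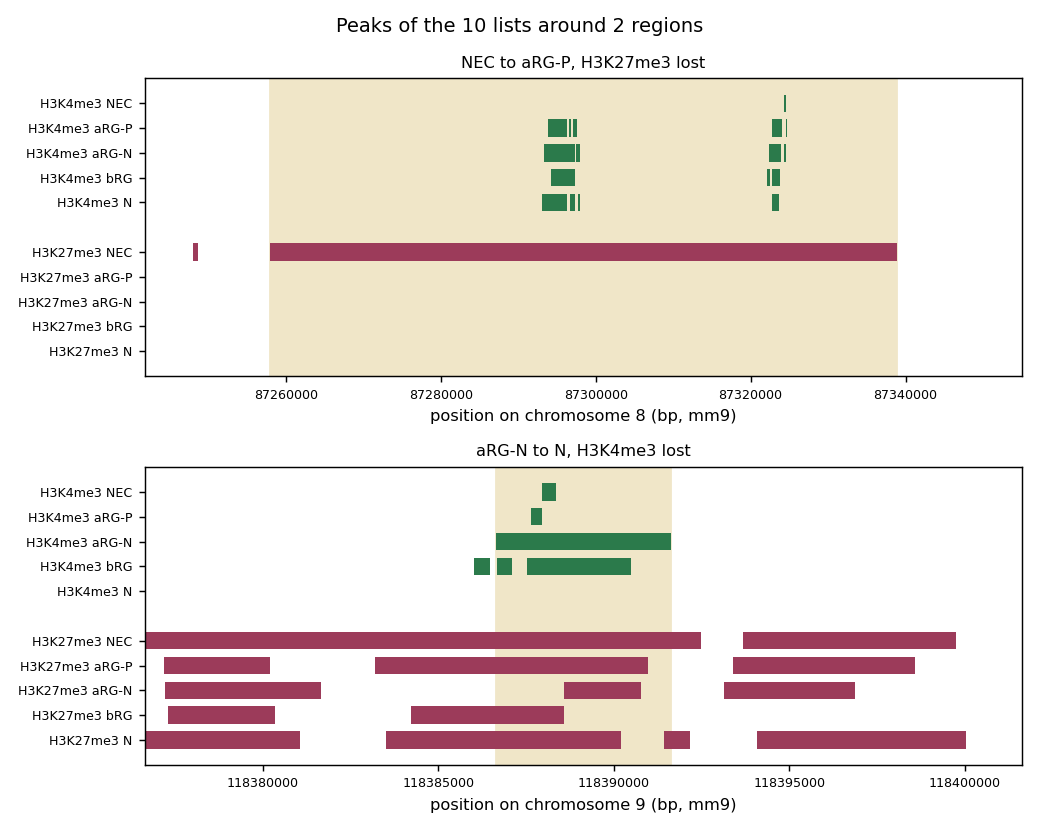
Peaks of the 10 lists (rows; H3K4me3 green, H3K27me3 purple) along chromosome 8 (top) and chromosome 9 (bottom), with position in bp on the horizontal axis and the named region shaded. On chromosome 8 the 80.9 kb H3K27me3 domain is drawn in NEC only, and on chromosome 9 the H3K4me3 peaks are drawn in the 4 progenitor lists and not in N.

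Chromosome X separated NEC from the other cell types. NEC had 3662 H3K27me3 peaks on X, 38.7% of its list, against 441 in aRG-P, 665 in aRG-N, 89 in bRG and 286 in N. On the autosomes the counts were 5798 in NEC and 4634, 6165, 3387 and 5448 in aRG-P, aRG-N, bRG and N. The NEC X peaks covered 8697 kb, against 1434 kb in aRG-N, the next list. They had a median width of 1389 bp and lay in 103 of 167 windows of 1 Mb, against 38 to 74 windows at E14.5. The 666 NEC H3K4me3 peaks on X lay in 112 windows, so 103 does not show a wider spread than that mark had. The scores of the NEC H3K27me3 peaks on X were low for the list, with a median at percentile 29.0. Among the 3476 highest-scoring peaks of each list, 128 NEC peaks lay on X, against 187 in aRG-P, 86 in aRG-N, 89 in bRG and 68 in N. Of the NEC X peaks, 6.01% overlapped an NEC H3K4me3 peak, against 62.3% of NEC autosomal peaks and 38.3% of autosomal peaks of like score. X peaks also met H3K4me3 less often than autosomal ones at E14.5, with 7.26% in aRG-P, 9.32% in aRG-N, 11.2% in bRG and 7.69% in N. The autosomal shares were 25.0%, 29.8%, 32.6% and 31.7% in this order, and 17.5%, 14.6%, 29.9% and 20.2% for peaks of like score. H3K4me3 peaks on X numbered 666 in NEC and 507, 523, 489 and 511 in aRG-P, aRG-N, bRG and N.

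**Figure D4:**
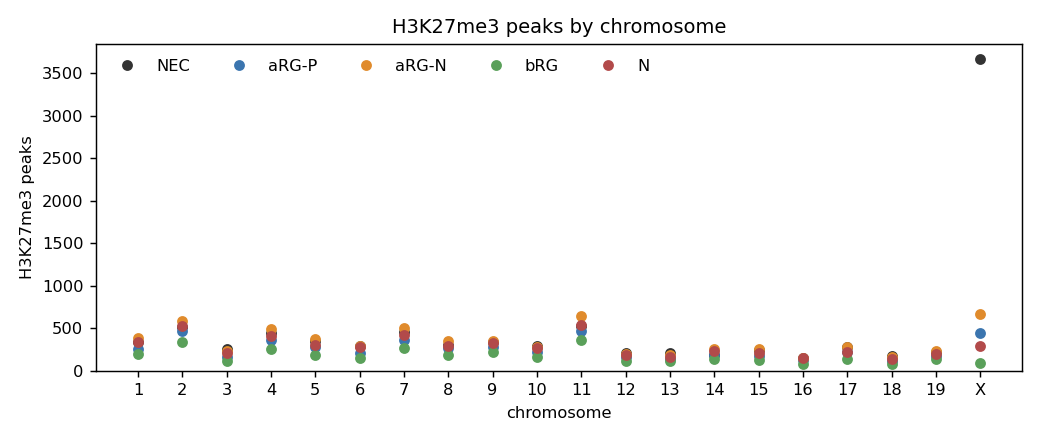
Number of H3K27me3 peaks (vertical axis) on each chromosome (horizontal axis), with 1 point per cell type. NEC stands at 3662 peaks on X, and the highest E14.5 list, aRG-N, at 665.

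The pair aRG-P and aRG-N asked what accompanies the change from proliferative to neurogenic division. H3K4me3 appeared at 1731 aRG-N peaks (11.7%) without an overlapping aRG-P peak, and 566 aRG-P peaks (3.54%) had none in aRG-N. The strongest site present in aRG-N and absent in aRG-P was on chromosome 8 from 97518140 to 97522709, with a fold enrichment of 14.3. It was also marked in bRG and carried no H3K4me3 in NEC or N and no H3K27me3 in any list. A site on chromosome 1 from 173985123 to 173987747 (fold enrichment 14.1) had H3K4me3 in aRG-N, bRG and N, and H3K27me3 in NEC only. Among aRG-P sites with no aRG-N peak within 5000 bp, the highest fold enrichment in the aRG-P list was 8.14, on chromosome 4 from 141155539 to 141155947. That site had H3K4me3 in the other 4 lists and H3K27me3 in all 5.

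H3K27me3 was present at 3185 aRG-N peaks (46.6%) without an aRG-P peak, and at 1071 aRG-P peaks (21.1%) without an aRG-N peak. The longest aRG-N domains absent in aRG-P were 30.7 kb on chromosome 13 (99329794 to 99360517), 29.7 kb on chromosome 4 (44517356 to 44547067) and 21.9 kb on chromosome 4 (130414326 to 130436199). The first was shared with NEC, bRG and N, and the other 2 were found in aRG-N alone. In the reverse direction the longest domain, on chromosome 12 from 120081107 to 120084989, measured 3.88 kb. In lists of equal length the H3K27me3 counts were 883 and 675. Unshared H3K4me3 peaks of both lists were weak, with median fold enrichments of 5.07 in aRG-N and 4.71 in aRG-P against 13.0 and 9.33 for shared ones. The labels call the 2 aRG-N H3K27me3 samples technical replicates.

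The comparisons of bRG with both apical types asked which marks separate basal from apical progenitors. The strongest bRG H3K4me3 site absent in aRG-P and in aRG-N was the same one, on chromosome 4 from 123363292 to 123364469 (fold enrichment 10.8), which was also marked in NEC and N. A site on chromosome 8 from 86528218 to 86528919 (7.50) had H3K4me3 in bRG alone. Sites marked in NEC, aRG-P and aRG-N and not in bRG or N included chromosome 5 from 146041245 to 146042273 (fold enrichment 13.3 in aRG-N), chromosome 4 from 57156172 to 57156508 (10.3 in aRG-P) and chromosome 17 from 8358506 to 8358766 (8.997 in aRG-P). None of these 3 carried H3K27me3 in any list.

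Against aRG-P, 1123 H3K4me3 peaks were lost and 1248 gained in bRG. With no peak allowed within 5000 bp the counts were 398 and 372, so which was larger depended on the rule. Against aRG-N, 1496 were lost and 386 gained. For H3K27me3, 2321 aRG-P peaks and 3998 aRG-N peaks were absent in bRG, and bRG had 579 and 325 peaks absent in them. Among H3K27me3 domains of aRG-P and aRG-N, the longest missing in bRG was the aRG-N domain of 29.7 kb on chromosome 4 named above. A domain on chromosome 10 (67012605 to 67038238 in aRG-N, 25.6 kb) was present in aRG-P, aRG-N and N and absent in bRG and NEC. A domain on chromosome 11 (98177104 to 98192561 in aRG-P, 15.5 kb) was present in NEC, aRG-P and aRG-N and absent in bRG and N, while H3K4me3 was present there in all 4 E14.5 lists. The longest bRG domains absent in aRG-N were 9.04 kb on chromosome 14 (118624844 to 118633881) and 6.52 kb on the same chromosome (62302720 to 62309238), both also found in NEC and N. In lists of equal length, 1011 aRG-P and 960 aRG-N peaks were absent in bRG, and 849 and 642 bRG peaks were absent in them.

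The comparison of progenitors with neurons asked what changes on differentiation. The 3 strongest aRG-N H3K4me3 sites absent in N were marked in all 4 progenitor lists, and in N each overlapped an H3K27me3 peak. They were on chromosome 9 from 118386640 to 118391640 (fold enrichment 20.3), chromosome 2 from 105508735 to 105511186 (17.8) and chromosome 4 from 154008655 to 154012900 (16.2). The first had H3K27me3 in all 5 lists. Its H3K4me3 peaks in NEC (118387957 to 118388353) and aRG-P (118387641 to 118387952) were short. The last 2 had it in NEC, aRG-P, bRG and N and lacked it in aRG-N only. In all, 293 of the 12488 aRG-N H3K4me3 peaks found in every progenitor list (2.35%, interval 2.09 to 2.63%) were absent in N. The count was 174 with no N peak allowed within 5000 bp and 141 with a −log10 q of at least 5. Of the 293, 136 (46.4%) overlapped H3K27me3 in N, against 11.8% of the peaks kept in N. In aRG-N itself the shares were 32.8% and 11.7%, and 43 of the lost peaks had H3K27me3 in N and not in aRG-N. The lost peaks were weaker, with a median fold enrichment of 6.77 in aRG-N against 13.3 for those kept. In every cell type the H3K4me3 peaks with H3K27me3 were the weaker ones. The shares were not matched for fold enrichment, so weak peaks could account for the excess.

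The 252 N H3K4me3 peaks found in no progenitor list (1.60%) had a median fold enrichment of 4.67, against 8.26 for the rest, and 38 of them lay over 5000 bp from any progenitor peak. The strongest were on chromosome 13 from 4244576 to 4244863 (6.61), chromosome 2 from 52413020 to 52414072 (6.61) and chromosome 2 from 37371820 to 37373091 (6.34). None of these carried H3K27me3 in any list. Against aRG-N alone, 1602 H3K4me3 peaks were lost and 861 gained, and the strongest gain was again the chromosome 4 site marked in bRG (11.8 in N). A site on chromosome 11 from 98789053 to 98790162 (10.2) was marked in every list except aRG-N.

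Of 2299 aRG-N H3K27me3 domains found in every progenitor list (median width 4646 bp in those kept in N), 30 (1.30%, interval 0.882 to 1.86%) were absent in N. The 2299 had to be in all 4 progenitor lists, the short bRG list included, which selects widely shared domains. The low share lost therefore does not measure how stable H3K27me3 is. Against aRG-N alone, without this selection, 40.5% of aRG-N peaks were absent in N. In lists of equal length 62 were lost and 366 gained. These 2 counts follow unlike rules and cannot be set against each other, since a gained peak had to be in no progenitor list. Of the 30, 23 overlapped H3K4me3 in N and 19 already did in aRG-N, with 4 doing so in N and not in aRG-N. Of the domains kept in N, 45.3% overlapped H3K4me3 there. Of the 30, 27 had no N peak within 5000 bp. The longest of these lay on chromosome 1 from 4477567 to 4495178 (17.6 kb) and had no H3K4me3 in N. The next, on chromosome 9 from 58041198 to 58052189 (11.0 kb), had H3K4me3 in every list except aRG-N. N had 942 H3K27me3 peaks found in no progenitor list, with a median width of 841 bp against 2562 bp for the rest. The longest were 8.73 kb on chromosome 14 (122799978 to 122808710), 7.16 kb on chromosome 10 (119851101 to 119858258) and 6.63 kb on chromosome 3 (131148357 to 131154985). Against aRG-N alone, 2768 H3K27me3 peaks were lost and 1543 gained. In lists of equal length these counts were 859 and 838, a closeness that the cut itself brings about. The longest gain over aRG-N, on chromosome 12 from 120074264 to 120096057 (21.8 kb), was also present in NEC, aRG-P and bRG.

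In the lists as deposited, sites with both marks were most frequent in NEC, a ranking that depended on how list lengths were treated. Both marks here means overlapping peaks of separate lists, each called on combined samples of many cells. Such overlap does not show both marks in the same cells or on the same copy of a chromosome. H3K4me3 peaks overlapping an H3K27me3 peak of the same cell type numbered 4630 in NEC (25.9%, interval 25.3 to 26.6%), 1423 in aRG-P (8.90%, 8.47 to 9.36%) and 2130 in aRG-N (14.4%, 13.8 to 15.0%). In bRG there were 1268 (8.41%, 7.97 to 8.86%) and in N 2009 (12.7%, 12.2 to 13.3%). Randomly placed H3K4me3 peaks overlapped H3K27me3 in at most 1.59% of cases, with placements not kept near transcripts. In every cell type the H3K4me3 peaks with H3K27me3 were weaker, with median fold enrichments of 12.8 against 22.7 in NEC and 6.34 against 8.53 in N.

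At the 11690 regions with H3K4me3 in all 5 lists, H3K27me3 was present at 21.3% in NEC, 9.33% in aRG-P, 12.9% in aRG-N, 8.96% in bRG and 13.3% in N. H3K27me3 was present in all 5 cell types at 723 of these regions, in NEC only at 907 and in E14.5 lists only at 376. Of the 4630 NEC peaks with both marks, 27.5% had both in aRG-P, 36.5% had H3K4me3 alone, 26.8% had H3K27me3 alone and 9.22% had neither. In aRG-N and N, whose H3K27me3 lists are longer than that of aRG-P, 40.6% and 34.0% had both. From aRG-N to N, 1235 of 2130 such peaks (58.0%) had both, 443 had H3K4me3 alone and 426 had H3K27me3 alone. Lists cut to equal length gave 17.1% with both marks in NEC and between 7.09% in aRG-P and 11.6% in aRG-N at E14.5. With H3K27me3 lists cut to equal covered length on the autosomes, 9.17% of 11345 autosomal regions with H3K4me3 in all 5 lists had H3K27me3 in bRG, whose list was the shortest and was left whole. The shares were 6.79% in NEC, 5.49% in aRG-P, 3.11% in aRG-N and 4.13% in N.

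**Figure D5:**
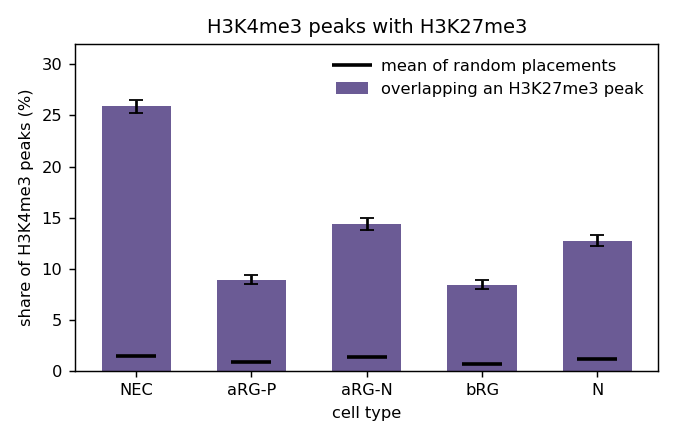
Share of H3K4me3 peaks (vertical axis, %) that overlap an H3K27me3 peak of the same cell type, for each cell type, with exact 95% binomial intervals as error bars and the mean of 100 random placements as black lines. NEC stands at 25.9% and the E14.5 lists between 8.41% and 14.4%.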

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

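No paired analysis was possible because each list combined its samples and no result came from a test between samples. For the same reason leaving out replicates was not possible. The autosome, common-score and chromosome X alternatives were chosen after seeing the data, and the other alternatives were planned. The planned −log10 q of at least 3 for H3K27me3 gave no values of its own because it removed no peak, and the promoter windows were not run. The unknown depth limits how far an absent peak can be read as an absent mark. Joining peaks across 3000 bp kept all 10 peak counts within 1.5 times but changed the order of the H3K4me3 lists. The aRG-N list, the shortest as deposited (14801), was then the longest at E14.5 (12104, against 11517 to 11618). The order of H3K4me3 list lengths therefore depended on how peaks were split. Counts of lost and gained peaks and whole-list peak counts not named below stayed within 1.5 times, and shares not named stayed within their interval. Losses minus gains are named only where their sign reversed. The cause of the shifts was not tested, except that shorter lists and stricter rules leave fewer peaks by construction.

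With a −log10 q of at least 5 for H3K4me3, lost counts were 258 (aRG-P to aRG-N), 564 (aRG-P to bRG), 926 (aRG-N to bRG) and 141 (progenitors to N). Gained counts were 222 (NEC to aRG-P), 654 (aRG-P to bRG), 151 (aRG-N to bRG) and 142 (progenitors to N), so losses minus gains for progenitors to N reversed to -1. For progenitors to N, losses and gains follow unlike rules, so their difference shows no net change. Shared H3K4me3 was 89.7% (NEC and aRG-N), 86.3% (NEC and bRG), 87.1% (NEC and N), 92.8% (aRG-P and bRG) and 92.3% (aRG-N and N). Both marks were found at 7.65% in aRG-P, 13.3% in aRG-N, 7.39% in bRG and 11.9% in N.

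With no peak allowed within 5000 bp, H3K4me3 losses were 2317, 173, 398, 698, 819 and 174 for NEC to aRG-P, aRG-P to aRG-N, aRG-P to bRG, aRG-N to bRG, aRG-N to N and progenitors to N. Gains in this order were 93, 749, 372, 101, 301 and 38. Losses minus gains for aRG-P to bRG reversed to 26. H3K27me3 gains were 373 (aRG-P to bRG) and 592 (progenitors to N).

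With an overlap of at least 50%, shared H3K4me3 of NEC was 84.4% with aRG-P, 87.7% with aRG-N, 84.9% with bRG and 84.7% with N. Shared H3K4me3 of aRG-P was 91.5% with aRG-N, 90.8% with bRG and 90.0% with N. It was 93.2% for aRG-N and bRG, 90.9% for aRG-N and N and 91.4% for bRG and N. Shared H3K27me3 of NEC in the same order was 42.8%, 47.8%, 38.9% and 45.6%. That of aRG-P was 61.7%, 63.0% and 62.9%. It was 56.6% for aRG-N and bRG, 63.2% for aRG-N and N and 64.3% for bRG and N. Both marks were found at 20.6% in NEC, 7.29% in aRG-P, 11.5% in aRG-N, 6.46% in bRG and 10.3% in N.

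In lists of equal length (14801 H3K4me3 and 3476 H3K27me3 peaks), H3K4me3 losses were 2365 (NEC to aRG-P), 333 (aRG-P to aRG-N) and 746 (aRG-P to bRG). H3K27me3 losses were 1361 (NEC to aRG-P), 675 (aRG-P to aRG-N), 1011 (aRG-P to bRG), 960 (aRG-N to bRG), 859 (aRG-N to N) and 62 (progenitors to N). H3K27me3 gains were 883 (aRG-P to aRG-N), 642 (aRG-N to bRG), 838 (aRG-N to N) and 366 (progenitors to N). Shared H3K4me3 of NEC was 90.2% with aRG-P, 93.1% with aRG-N, 91.3% with bRG and 90.1% with N. It was 91.4% for aRG-P and aRG-N and 91.3% for aRG-N and N. Shared H3K27me3 of NEC in the same order was 62.0%, 66.7%, 62.7% and 65.8%. That of aRG-P was 77.6% with aRG-N, 73.2% with bRG and 73.6% with N. It was 77.0% for aRG-N and bRG, 75.6% for aRG-N and N and 79.2% for bRG and N. Both marks were found at 17.1% in NEC, 7.09% in aRG-P, 11.6% in aRG-N and 9.72% in N. On X, H3K27me3 peaks numbered 128 in NEC, 187 in aRG-P, 86 in aRG-N and 68 in N, and stayed at 89 in bRG.

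With the common lowest H3K27me3 score, NEC kept 6124 peaks, 1436 of them on X, against 220 in aRG-P, 665 in aRG-N, 74 in bRG and 281 in N. H3K27me3 losses were 3560 (NEC to aRG-P), 416 (aRG-P to aRG-N) and 1222 (aRG-P to bRG), and the gain from NEC to aRG-P was 1059. Shared H3K27me3 of NEC was 53.1% with aRG-P, 55.7% with aRG-N, 51.6% with bRG and 56.1% with N. It was 60.5% for aRG-P and aRG-N, 73.3% for aRG-P and bRG, 64.7% for aRG-P and N and 57.0% for aRG-N and bRG. Both marks were found at 23.4% in NEC and 8.07% in aRG-P. On autosomes only, the H3K27me3 loss from NEC to aRG-P was 2921.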

Other observations

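The tests on chromosome X and on the bRG list were chosen after the result was seen, and so was the equal-number comparison of sites with both marks. The other 2 tests of sites with both marks were recorded as chosen before. Some predictions and rules for reading the tests were changed after values were seen, which may include these 2. In all 5 cell types the 4 longest H3K27me3 domains lay on chromosomes 15, 6, 11 and 2. In bRG they measured 148.4 kb (chromosome 15, 102731065 to 102879484), 134.3 kb (chromosome 6, 52096977 to 52231307), 129.6 kb (chromosome 11, 96110623 to 96240255) and 123.4 kb (chromosome 2, 74481306 to 74604666). The fifth longest in bRG, on chromosome 9 from 91251835 to 91317166, measured 65.3 kb. The GRCm38.p6 gene table places runs of 9 to 11 Hox genes, which pattern the body axis, on those same 4 chromosomes. Whether the domains are those gene clusters was not tested, since the builds differ and positions could not be compared.

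NEC had 9.89 times the mean E14.5 number of H3K27me3 peaks on X and 1.18 times the mean on the autosomes, and against aRG-N alone 5.51 and 0.940 times. The transcript filter does not account for it, since peak numbers on X before the filter were 6.07 times those of the next list. H3K4me3 gave little sign of higher X coverage for any antibody, its X ratio being 1.14 times the autosomal one. This ratio counts peaks, which need not rise with coverage. The median H3K4me3 fold enrichment on X was 0.564 times the autosomal one in NEC, against 0.632 to 0.714 in the E14.5 lists. Weak peaks in the longer NEC list could also lower that median. A longer or more sensitive NEC list as the only cause is argued against by aRG-N, since the NEC to aRG-N ratio on X was 5.86 times that on the autosomes and 2.84 times with one lowest score for all lists, but the excess sat in low-scoring peaks and sensitivity may still contribute: in lists of equal length 128 NEC peaks lay on X, below 187 in aRG-P and above 86 in aRG-N, 89 in bRG and 68 in N. H3K27me3 spread along an inactive X stays open. NEC X peaks met H3K4me3 at 0.157 times the share of autosomal peaks of like score, below the other lists (0.375 to 0.638). The intervals (0.137 to 0.178 in NEC, lowest bound elsewhere 0.184) cover the X share only and take the autosomal share as fixed. That autosomal share was 38.3% in NEC against 14.6 to 29.9% in the other lists, which lowers the NEC ratio. The NEC X share itself, 6.01% (5.26 to 6.83%), was not separable from 7.26% in aRG-P (5.02 to 10.1%). The sex of the embryos is not in the labels, and age and cell type differ together.

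The short bRG H3K27me3 list may reflect lower sensitivity. Of aRG-N peaks with the lowest scores (the first of 4 equal parts), 4.22% were found in bRG, against 94.9% of those with the highest, a ratio of 22.5. The same ratio was 8.36 for aRG-P, 4.94 for N and 2.89 for NEC. Most bRG peaks were not separate from the other E14.5 lists. In lists of equal length bRG peaks were found there in 80.2% of cases on average, against 74.1 to 75.7% for those lists. The higher bRG share does not argue against some separate regions, since peak number was matched and covered length was not. On the autosomes 1163 aRG-N, 1349 N or 2068 aRG-P peaks covered about the same 12.4 Mb as 3387 bRG peaks. A true reduction of H3K27me3 in bRG stays open, as untested.

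More sites with both marks in NEC did not come from extra weak H3K4me3 peaks alone, since at regions with H3K4me3 in all 5 lists the NEC share was 1.60 times the highest E14.5 share. Whether a more sensitive NEC H3K27me3 list could produce it cannot be told apart from a difference in the cells. With H3K27me3 lists cut to the same covered autosomal length the ratio to the highest E14.5 list was 0.740, the outcome that explanation predicted, but with lists cut to the same number of peaks it was 1.36. The 0.740 rests on bRG alone, which that cut left whole with 3387 peaks, and the NEC share of 6.79% lay above those of aRG-P, aRG-N and N (5.49%, 3.11% and 4.13%). Embryonic age and cell type differ together in this comparison and stay open.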
